A study of Saccharomyces cerevisiae with 116 samples.

How the data were processed

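RNA was measured in 116 libraries of S. cerevisiae BY4741: 16 with added S. pombe cells, 50 without, and 50 from sucrose gradient fractions and inputs with added S. pombe RNA. Per the labels, cells grew in YPD for 7 to 10 generations and were treated for 2 h with alpha factor (25 uM) or nocodazole (10 ug/ml), with 3.5 h of nocodazole or cycloheximide in some libraries. The unit of the cycloheximide labels 0.1 and 0.2 is not given in the sources used here, nor is the meaning of the time label t0'; T15 to T60 were read as minutes. Per the labels RNA was extracted with hot phenol, depleted of ribosomal RNA with Ribo-Zero and made into ScriptSeq v2 libraries, and gradient fractions into TruSeq Stranded Total RNA libraries.

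The deposited values are raw read counts per open reading frame (ORF) and, where added, per S. pombe transcript; per the submitters' processing notes the authors trimmed reads with Trimmomatic 0.32, aligned them with Bowtie2 (version not given in the sources used here) and counted them with HTSeq 0.6.1. Genome build, annotation and strand setting are not given in the sources used here. The values were checked to be whole numbers with totals that differ between libraries. The tables hold 6705 (unspiked), 6708 (spiked) and 6709 (fractions) ORF rows, of which 6018, 6021 and 6022 matched a gene symbol in the RefSeq R64 gene table. Emptied lines (8, 4 and 4), 2-micron plasmid rows and 1 row without a name (0.00229 to 0.00502% of a library) were left out. 70 deposited count columns that match no labelled sample (alpha factor T0 replicate 2, alpha factor T30 and dot6 tod6 fractions) were not used here.

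S. cerevisiae totals had medians of 2617628 (spiked), 3960115 (unspiked) and 1653398.5 (fractions), and S. pombe counts made up 5.53 to 14.2% of spiked and 5.70 to 49.4% of fraction libraries. No 2 libraries of a group were copies of each other: their counts differed by at least 5.39 times the sampling variance (chi-square per degree of freedom).

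Libraries were grouped by the labels' cell state, treatment, stress and time. Each series was fitted once: spiked (16 libraries), unspiked salt at T0 and T30 (22), unspiked heat at T0 and T10 (12), and the 6R> fraction with its input in asynchronous cells (8). The labels 0.5N, 0.7N and no dose, and 33c, 37c and no temperature, were pooled as replicates, and the 0.5N and 0.7N (33c and 37c) libraries share replicate number 2. Genes passing filterByExpr were scaled by TMM and tested by quasi-likelihood F tests in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between responses were tested as interaction contrasts. The spiked comparisons were repeated with S. pombe totals as library sizes. The polysome ratio, the log2 ratio of each gene's counts in fractions 2R and above to those in RNP, 40S, 60S and 80S, was computed after scaling fractions by S. pombe counts (offset 1 read in the deepest library), on the assumption of equal S. pombe RNA per fraction, for genes with at least 10 CPM on average over the inputs of both times, and compared with limma. A second test, chosen after the data were seen, asked for that minimum at each time. Total ratios were compared by exact two-sided permutation and sign-flip tests. Standard errors are those of the fitted log2 changes.

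The gene lists were written before the data were examined, from general knowledge of the genes. The deposited iESR, RP and PAC lists were taken from an annotation column of the deposited tables. A list of alpha mating type genes had 4 matched members, under the minimum of 5, and was not tested. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, which tests the direction of the set only, on log2 CPM with a prior count of 2. An adjusted p for a list is adjusted over the lists of 1 comparison, and counts adjusted over the list alone use the list's own genes.

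Named genes follow a rule fixed before the data were examined: per comparison the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM (counts scaled to library size); for each list discussed up to 4 called members with the largest change, or the member with the largest p where none was called; and always CTT1, HSP12, GPD1, STL1, NSR1, RPL3, FUS1, CLB2, CLN2 and TDH3 where they bear on the comparison, with HIS3, LEU2, MET17 and URA3 as a strain check.

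Whether replicate numbers pair samples was checked by correlating residuals of libraries from different groups. In the spiked series libraries with the same number correlated at 0.313 to 0.706 (median 0.597, 18 pairs) and those with different numbers at -0.652 to 0.184 (median -0.276, 36 pairs), so the numbers were read as pairs there and a replicate block was run as an alternative. They were read as pairs too for cycloheximide 0.1 and 3.5 h nocodazole (same number 0.201 to 0.654) and for the heat series without its alpha T10 libraries (0.419 to 0.798). Other alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, only the libraries compared, a 2-fold minimum, and leaving out each library. Single libraries were compared with 10000 random lists of matched level. Each test was run on simulated data with 200 changed genes in each of 18 comparisons: 2-fold changes were recovered in 0 to 55% and 4-fold changes in 11 to 99% of cases, with at most 13 unchanged genes called and 0 with the wrong sign. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.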

Results

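The series holds RNA libraries of budding yeast strain BY4741 exposed to salt (NaCl) or heat shock while growing, or while held by alpha factor (G1), nocodazole (mitosis) or cycloheximide (a translation inhibitor). The question that the titles and labels put is how far the stress response of growth genes and of defense genes depends on whether cells divide and grow. 16 RNA libraries carried added fission yeast (S. pombe) cells: asynchronous cells and alpha-factor-arrested cells before salt (T0) and at T30, 3 libraries in each of these 4 groups, and cycloheximide at the labels 0.1 and 0.2, 1 library per time. 50 RNA libraries had no added cells and covered salt and heat in alpha-factor and nocodazole arrest. 50 libraries came from sucrose gradient fractions and their inputs, with added S. pombe RNA. S. cerevisiae counts per library were 1555271 to 5469230 (spiked), 1794997 to 7043273 (unspiked, median 3960115) and 365088 to 5081617 (gradient fractions). LEU2, MET17 and URA3, which are deleted in BY4741, stayed at or under 2.89 CPM in every library, while the partly deleted HIS3 was read at 10.1 to 141 CPM. The labels call the libraries replicates without saying that each came from its own culture, so p-values measure only the spread between these samples.

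Salt in growing cells, the reference for all later comparisons, raised nearly all genes of the general stress list and, on the scale of total S. cerevisiae counts, lowered nearly all ribosomal protein genes. STL1, the glycerol transporter of the plasma membrane, rose from 1.43 ± 1.25 to 2479 ± 1040 CPM (mean ± SD, n = 3 and 3), a log2 change of 10.45 ± 0.60 (± SE throughout), and HSP12, a small membrane-protecting stress protein, rose by 9.68 ± 0.56. The transketolase isozyme TKL2 (9.35 ± 0.56), the hexose transporter HXT5 (9.24 ± 0.68) and YNL194C (9.08 ± 0.75) completed the 5 largest rises. The 5 largest falls were the mating-type endonuclease HO (-4.49 ± 0.43), the adenine deaminase AAH1 (-4.21 ± 0.24), and 3 genes of phosphate metabolism, PHM6 (-4.0 ± 0.44), the phosphate transporter PHO84 (-3.98 ± 0.53) and the acid phosphatase PHO12 (-3.97 ± 0.30). In all, 1275 of 5744 tested genes rose and 1124 fell (edgeR, adjusted p under 0.05), and 772 and 753 of these changed at least 2-fold. Catalase CTT1 (7.30 ± 0.50) and the glycerol-3-phosphate dehydrogenase GPD1 (5.49 ± 0.28) rose. The nucleolin-like NSR1 (-3.14 ± 0.38) and RPL3 (-1.52 ± 0.20) fell. TDH3 of glycolysis (-0.41 ± 0.25, adjusted p = 0.214, called with the replicate pairs as a block) and the pheromone gene FUS1 (0.09 ± 0.26, adjusted p = 0.812) did not pass.

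The growth lists moved down nearly as whole lists with salt in asynchronous cells on the scale of total S. cerevisiae counts. Of the cytosolic ribosomal protein genes 133 of 137 (134 adjusted over the list alone) fell, with a median log2 change of -1.65 (adjusted p = 3.14e-35, and adjusted p = 0.0746 with an estimated correlation), among them RPS26B (-2.68 ± 0.27), RPL35B (-2.19 ± 0.32) and RPS10A (-2.17 ± 0.25). When scaled to S. pombe counts 38 of 137 (42 adjusted over the list alone) fell, median -1.05, and 71 of 129 (87 adjusted over the list alone) biogenesis genes, median -1.52. Of the ribosome biogenesis genes 122 of 129 (126 adjusted over the list alone) fell, median -2.04 (adjusted p = 1.67e-31, and adjusted p = 0.129 with an estimated correlation), with UTP23 (-3.33 ± 0.43), the helicase DHR2 (-3.21 ± 0.39) and RRP5 (-3.20 ± 0.35) at the lower end. RNA polymerase I and III genes fell in 16 of 21 (19 adjusted over the list alone), including RPA190, the largest subunit of polymerase I (-2.64 ± 0.25), and RPA43 (-3.01 ± 0.44), with median -1.53 (adjusted p = 1.3e-08, and adjusted p = 0.0746 with an estimated correlation). Translation factors fell in 30 of 36 (31 adjusted over the list alone), median -0.96, for example the elongation factor YEF3 (-1.88 ± 0.23), and kept the call with either correlation (adjusted p = 7.79e-12 and 0.0386). The general stress list rose in 66 of 67 (66 adjusted over the list alone), median 3.69, with PHM7 (8.32 ± 0.54) and the transaldolase isozyme NQM1 (8.19 ± 0.53). The osmotic list rose in 26 of 31 (26 adjusted over the list alone), median 3.50, with RTC3 (8.91 ± 0.55) and the aldehyde dehydrogenase ALD3 (8.12 ± 0.40). Both calls held with either correlation (adjusted p = 8.69e-36 and 0.0386; 1.57e-16 and 0.0386). In the 3 replicate pairs the general stress medians were 3.66, 3.63 and 3.67, and the ribosomal protein medians -1.84, -1.31 and -1.79. The deposited lists, which are no independent evidence, moved likewise. 248 of 273 (251 adjusted over the list alone) of the induced stress list rose, and 119 of 128 (120 adjusted over the list alone) of the deposited ribosomal protein list and 371 of 436 (383 adjusted over the list alone) of the deposited PAC list fell, with medians 2.03, -1.61 and -1.46. Reads of near-identical paralogs, as in most ribosomal protein pairs, and of overlapping or dubious frames (YCL074W, YCL076W, YGL123C-A) could not be assigned with certainty.

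Other lists moved less with salt in asynchronous cells. G2/M genes fell in 14 of 29 (14 adjusted over the list alone), CLB2 among them (-1.22 ± 0.22), with median -0.54 (adjusted p = 0.000614, and adjusted p = 0.0386 with an estimated correlation). G1/S genes fell in 12 of 40 (10 adjusted over the list alone) with median -0.72 (adjusted p = 0.00203, and adjusted p = 0.557 with an estimated correlation). M/G1 genes fell in 9 of 25 (9 adjusted over the list alone), median -0.41 but 0.14 when scaled to S. pombe counts (adjusted p = 0.000769, and adjusted p = 0.215 with an estimated correlation). Histone genes fell in 5 of 10 (7 adjusted over the list alone), median -0.75 (adjusted p = 0.00487, and adjusted p = 0.122 with an estimated correlation). Proteasome genes rose in 16 of 35 (21 adjusted over the list alone), median 0.51 (adjusted p = 0.000251, and adjusted p = 0.122 with an estimated correlation), with PRE4 (0.99 ± 0.19) and RPT3 (0.90 ± 0.14). Amino acid synthesis genes fell in 22 of 41 (24 adjusted over the list alone) (adjusted p = 1.22e-05, and adjusted p = 0.35 with an estimated correlation), with MET6 (-2.17 ± 0.19) and HIS1 (-2.05 ± 0.23), while the arginine gene ARG3 rose (1.74 ± 0.40). Nuclear respiration genes rose in 12 of 33 (12 adjusted over the list alone) (adjusted p = 0.00772, and adjusted p = 0.498 with an estimated correlation), as SDH1 did (1.71 ± 0.42), while cytochrome c gene CYC1 fell (-2.85 ± 0.30). Of the meiosis list, a check for another cell state, 6 of 17 (6 adjusted over the list alone) rose, led by SPS100 (6.56 ± 0.52), with adjusted p = 0.00203 and 0.0386 for the 2 correlations. Glycolysis genes had a median of -0.43, but 0.17 when scaled to S. pombe counts (adjusted p = 0.0384, and adjusted p = 0.681 with an estimated correlation), and lost the call without asynchronous T0 replicate 1 (adjusted p = 0.187) or without T30 replicate 3 (adjusted p = 0.228). Not called were heat shock factor targets (13 higher and 10 lower of 33, adjusted p = 0.297, SSA4 at 4.53 ± 0.34 and HSP26 at 4.37 ± 0.25) and cell wall integrity genes (6 higher, 2 lower of 22, adjusted p = 0.599, CWP1 at 3.56 ± 0.20). Nor were 3 lists whose medians lay below 0 here and above 0 when scaled to S. pombe counts. They included the pheromone genes (3 higher, 11 lower of 32, adjusted p = 0.116) and the mitochondrial ribosomal proteins (median -0.05, 1 higher, 3 lower of 70, adjusted p = 0.297). The last was the genes encoded in mitochondria (median -0.32, 0 of 8 in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2, adjusted p = 0.32).

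Alpha-factor-arrested cells, the test of salt without division, raised defense genes, while growth genes fell by less on the scale of total S. cerevisiae counts, and most of the ribosomal protein genes did not pass. STL1 (8.42 ± 0.56), TKL2 (7.45 ± 0.53), YER053C-A (6.10 ± 0.63), GRE1 (5.59 ± 0.43) and ALD3 (5.31 ± 0.35) were the 5 largest of 314 rises among 5744 tested genes (edgeR). AAH1 (-2.56 ± 0.22), the methyltransferase IME4 (-2.29 ± 0.26), the cell wall glucanase SCW11 (-2.19 ± 0.46), FRE7 (-2.14 ± 0.43) and SFG1 (-2.03 ± 0.33) were the 5 largest of 208 falls. YER053C-A had 2 counts over the 3 libraries before salt, a ratio of 90.1 (24.6 to 750, counting error only, as for all such intervals). CTT1 (4.95 ± 0.45), HSP12 (5.12 ± 0.45), GPD1 (2.66 ± 0.24), YGP1 (5.30 ± 0.30), the small heat shock proteins HSP26 (2.60 ± 0.24) and HSP42 (2.61 ± 0.35), SPS100 (4.99 ± 0.47), CWP1 (2.15 ± 0.19) and ARG3 (3.54 ± 0.40) rose. NSR1 (-1.92 ± 0.36), DHR2 (-1.74 ± 0.37), the helicase DBP2 (-1.62 ± 0.28), SDA1 (-1.55 ± 0.23) and MET6 (-1.45 ± 0.18) fell, while RPL3 was -0.51 ± 0.19 (adjusted p = 0.124).

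By list, general stress genes rose in 49 of 67 (57 adjusted over the list alone) with salt in alpha factor, median 1.78 (adjusted p = 1.74e-41, and adjusted p = 0.0594 with an estimated correlation). Osmotic genes rose in 22 of 31 (24 adjusted over the list alone), median 2.06 (adjusted p = 9.86e-25, and adjusted p = 0.0512 with an estimated correlation). The deposited induced stress list rose in 104 of 273 (138 adjusted over the list alone), median 0.70 (adjusted p = 1.12e-35, and adjusted p = 0.0932 with an estimated correlation). Ribosome biogenesis genes fell in 28 of 129 (62 adjusted over the list alone), median -0.89 (adjusted p = 2.38e-22, and adjusted p = 0.285 with an estimated correlation). Polymerase I and III genes fell in 4 of 21 (11 adjusted over the list alone), median -0.62 (adjusted p = 4.89e-06, and adjusted p = 0.152 with an estimated correlation). Of the cytosolic ribosomal protein genes 3 of 137 (0 adjusted over the list alone) fell (RPL36A at -0.74 ± 0.21, RPS1A at -0.68 ± 0.15 and RPS23B at -0.57 ± 0.16), with a list median of -0.42, but 0.07 when scaled to S. pombe counts (adjusted p = 1.05e-11, and adjusted p = 0.334 with an estimated correlation). RPL36A lost the call without any 1 library but T30 replicate 3, RPS23B without any but T0 replicate 1 and with RLE size factors or no filter, RPS1A without T0 replicate 2 or T30 replicate 2, and all 3 with only the libraries compared. Pheromone genes fell in 12 of 32 (17 adjusted over the list alone), median -0.72 (adjusted p = 3.17e-10, and adjusted p = 0.145 with an estimated correlation), as did ASG7 (-1.44 ± 0.25), PRM2 (-1.49 ± 0.41) and FIG1 (-1.33 ± 0.35), with FUS1 at -0.45 ± 0.23 (adjusted p = 0.257). PRM2 and FIG1 lost the call without any 1 library but T30 replicate 1 and with only the libraries compared. 3 of 10 histone genes rose (5 over the list alone), HTA2 by 1.03 ± 0.24 (adjusted p = 0.00195, and adjusted p = 0.132 with an estimated correlation). The G1/S list had a median of 0.43 (adjusted p = 0.0284, and adjusted p = 0.701 with an estimated correlation) with CLB6 (4.29 ± 1.16), PCL1 (4.30 ± 0.98), YOX1 (4.04 ± 0.98) and CLN1 (2.50 ± 0.62) among its 5 rises, but T30 replicate 2 stood apart. PCL1 was read there at 116 CPM against 5.20 and 20.8 in the other 2 T30 libraries. The list median was -0.059 (adjusted p = 0.75) without it and 0.38 (adjusted p = 0.119) without T0 replicate 1. That library was also lowest for the pheromone list (median log2 CPM 8.22 against 9.08 and 8.84), whose fall was -0.51 without it and still called.

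With the replicate pairs as a block, 807 genes rose and 915 fell with salt in alpha factor, FUS1 and RPL3 among those added, and 61 of 137 ribosomal protein and 116 of 129 biogenesis genes fell, but 0 and 12 when scaled to S. pombe counts. In the 3 pairs the ribosomal protein medians were -0.39, -0.50 and -0.34, and the biogenesis medians -0.93, -1.02 and -0.74. When scaled to S. pombe counts they were -0.19, 0.08 and 0.24, and -0.73, -0.44 and -0.16. Without T0 replicate 2, T0 replicate 3 or T30 replicate 2 the count was 199, 252 or 317. Then 14, 11 or 12 of the 37 named genes called in this comparison no longer passed, as did 8, 3 and 5 without T0 replicate 1, T30 replicate 1 and T30 replicate 3.

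Whether arrest changed the salt response was tested as the difference between the 2 responses. 214 genes had a higher and 291 a lower salt change in alpha factor than in asynchronous cells (edgeR, 505 of 5744), or 7 and 61 when scaled to S. pombe counts, 10.3% against 42.4% higher. On that scale the medians moved little, from -1.90 to -1.93 for the general stress list and from 1.24 to 1.14 for the ribosomal protein list, while the spread between libraries grew (biological coefficient of variation 0.245 to 0.406). The ribosomal protein medians of the replicate pairs were then -1.03, -0.68 and -1.58 in asynchronous cells and -0.19, 0.08 and 0.24 in alpha factor. The lower responses included CPP3 (-5.07 ± 0.91), YNL194C (-4.78 ± 1.01), NQM1 (-4.78 ± 0.60), HSP12 (-4.56 ± 0.60), HXT5 (-4.46 ± 0.80), RTC3 (-4.44 ± 0.61), the sodium pump ENA1 (-3.66 ± 0.44), the repressor XBP1 (-3.53 ± 0.46), TMA10 (-3.24 ± 0.58), the Hsp70 SSA4 (-2.75 ± 0.43), GPD1 (-2.84 ± 0.33) and CTT1 (-2.34 ± 0.57). STL1 (-2.04 ± 0.84, adjusted p = 0.154) and NSR1 (1.22 ± 0.49, adjusted p = 0.148) did not pass in the unblocked test. Higher responses, that is smaller falls or rises in place of falls, were those of CLB6 (6.28 ± 1.52, but 3.31 with adjusted p = 0.0752 without alpha T30 replicate 2, which stood apart for G1/S genes), MRH1 (4.29 ± 0.47), MNN1 (4.14 ± 0.72), PHO84 (3.57 ± 0.68), HO (3.39 ± 0.56), NRM1 (4.35 ± 0.76) and HOF1 (2.21 ± 0.51). So were those of RPS26B (1.96 ± 0.37), RPL7B (1.84 ± 0.50), RPS3 (1.67 ± 0.27), RPL3 (1.01 ± 0.27), UTP23 (2.11 ± 0.57), DBP3 (1.88 ± 0.51), BRX1 (1.86 ± 0.48), HTA1 (1.43 ± 0.26) and HTA2 (1.59 ± 0.32).

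In this difference the general stress list was lower in 45 of 67 (61 adjusted over the list alone), median -1.90 (adjusted p = 3.27e-31, and adjusted p = 0.0653 with an estimated correlation). The osmotic list was lower in 14 of 31 (17 adjusted over the list alone), median -1.09 (adjusted p = 6.01e-11, and adjusted p = 0.0653 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 64 of 137 (114 adjusted over the list alone), median 1.24 (adjusted p = 4e-39, and adjusted p = 0.0653 with an estimated correlation). Ribosome biogenesis genes were higher in 20 of 129 (39 adjusted over the list alone), median 1.18 (adjusted p = 1.81e-23, and adjusted p = 0.222 with an estimated correlation). Polymerase I and III genes were higher in 4 of 21 (7 adjusted over the list alone) (adjusted p = 6.15e-07, and adjusted p = 0.103 with an estimated correlation). Histone genes (6 of 10 (9 adjusted over the list alone), median 1.28) and G2/M genes (6 of 29 (7 adjusted over the list alone), median 0.42) were higher with either correlation (adjusted p = 1.55e-07 and 0.0414, then 0.000144 and 0.0414). G1/S genes were higher in 6 of 40 (17 adjusted over the list alone), median 1.15 (adjusted p = 2.19e-07, and adjusted p = 0.311 with an estimated correlation), and still called without alpha T30 replicate 2 (median 0.78). The pheromone median was -0.58 (adjusted p = 0.0461, and adjusted p = 0.682 with an estimated correlation), with adjusted p = 0.060 under the replicate block and 0.0825, 0.217 and 0.0836 without alpha T0 replicate 3, alpha T30 replicate 2 and asynchronous T30 replicate 2. The glycolysis median was 0.34 (adjusted p = 0.0509, and 0.0240 under the block).

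With the replicate pairs as a block this difference held 902 higher and 898 lower genes, NSR1 and STL1 added, and with DESeq2 383 and 375. The count was 236, 270, 300, 311, 316 and 333 without alpha T0 replicate 1, alpha T0 replicate 3, alpha T30 replicate 2, asynchronous T0 replicate 2, asynchronous T30 replicate 1 and asynchronous T0 replicate 3. In these fits 9, 6, 8, 7, 5 and 6 of the 28 named genes called in the difference no longer passed, as did 5 without asynchronous T30 replicate 3 or alpha T30 replicate 3. With S. pombe scaling 10 no longer passed (BRX1, DBP3, HOF1, HTA1, HTA2, RPL3, RPL7B, RPS26B, RPS3 and UTP23).

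**Figure D1:**
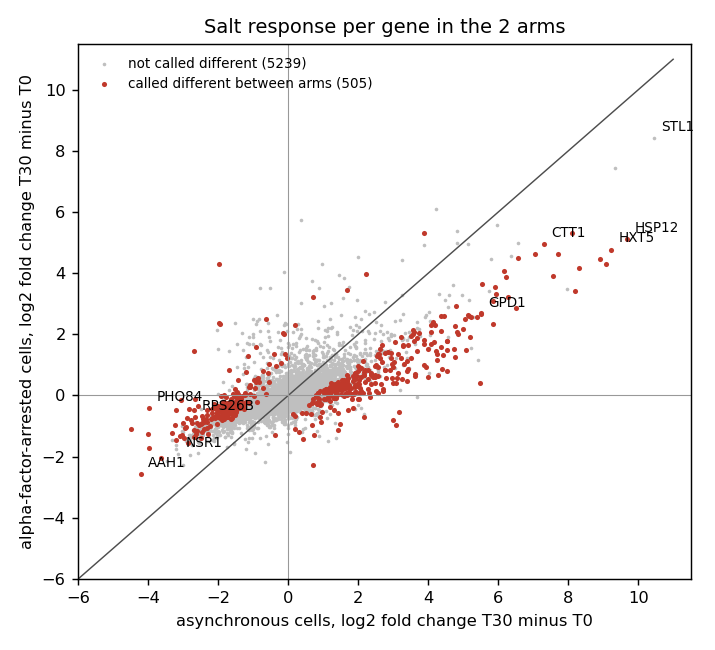
Salt change of each gene in asynchronous (horizontal) and alpha-factor-arrested cells (vertical). Pearson's r over 5744 genes was 0.726.

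Arrest itself was compared before salt, which also checks the labels. All 32 pheromone genes were higher in alpha factor, median 3.35 (adjusted p = 9.89e-46 and 0.00637 with an estimated correlation). FIG1 (11.71 ± 0.64), PRM3 (10.90 ± 0.58), PRM6 (10.32 ± 0.79), PRM2 (9.69 ± 0.66) and the overlapping frame YCL076W (10.75 ± 0.97) led. The fusion gene FUS1 was at 757 ± 44.1 against 20.8 ± 2.31 CPM (5.19 ± 0.28). PRM3 and PRM6 had 2 and 3 counts over the 3 asynchronous libraries, ratios of 2189 (606 to 18084) and 1384 (473 to 6712), and YCL076W had 0, at least 235-fold higher against 3 counts over the group. All 10 histone genes were lower, median -2.42 (adjusted p = 1.02e-18 and 0.00155), HTA2 by -4.20 ± 0.25 and HHF1 by -3.77 ± 0.19. G2/M genes were lower in 16 of 29 (17 adjusted over the list alone), median -0.87 (adjusted p = 1.79e-12 and 0.00127), with the cyclins CLB1 (-4.92 ± 0.31) and CLB2 (-1.97 ± 0.22), HOF1 (-4.70 ± 0.39) and the transcription factor SWI5 (-3.65 ± 0.26). G1/S genes were lower in 16 of 40 (29 adjusted over the list alone) (adjusted p = 6.94e-12, and adjusted p = 0.334 with an estimated correlation), with PCL1 (-5.10 ± 0.98), YOX1 (-4.42 ± 0.98), NRM1 (-4.33 ± 0.57) and the cohesin MCD1 (-4.28 ± 0.83). TOS6 (-4.58 ± 1.11) and IRC8 (-4.57 ± 0.35) were also among the 5 largest falls, TOS6 losing its call without alpha T0 replicate 1 or 3.

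Part of the defense genes were higher in arrest before salt. General stress genes were higher in 29 of 67 (40 adjusted over the list alone), median 0.87 (adjusted p = 3.44e-14 and 0.316 with an estimated correlation). Osmotic genes were higher in 12 of 31 (14 adjusted over the list alone), median 0.68 (adjusted p = 1.13e-06 and 0.311 with an estimated correlation). NQM1 (4.78 ± 0.48), the vacuolar mannosidase AMS1 (3.45 ± 0.36), HSP12 (3.40 ± 0.47), RTC3 (3.35 ± 0.48), ENA1 (3.04 ± 0.34) and GPD1 (1.92 ± 0.24) passed and CTT1 (0.87 ± 0.43) and STL1 (0.48 ± 0.74) did not. Of the cell wall integrity genes 8 of 22 (9 adjusted over the list alone) were higher (adjusted p = 0.00986, and adjusted p = 0.51 with an estimated correlation), the kinase SLT2 by 2.45 ± 0.16, and the glucan synthase GSC2 was higher by 4.0 ± 0.40. The ribosomal protein median was -0.34 with 3 of 137 (0 adjusted over the list alone) genes lower, namely RPL9A (-0.66 ± 0.20), RPL8B (-0.61 ± 0.18) and RPS1A (-0.48 ± 0.15) (adjusted p = 4.34e-08, and adjusted p = 0.51 with an estimated correlation). RPL9A and RPS1A lost the call without any 1 of the 6 libraries, RPL8B without any but alpha T0 replicate 2, and all 3 with no filter on low counts. The biogenesis median was -0.32 with 0 of 129 genes called in edgeR (2 lower at an unadjusted p under 0.05) and 0 in DESeq2 (adjusted p = 0.000136 and 0.709 with an estimated correlation). Both list counts are without the replicate block and may be too low. 494 of 5744 genes were higher and 243 lower (edgeR), 983 and 736 with the block, adding CTT1, and 484 in all without alpha T0 replicate 1. The genes encoded in mitochondria, a check of RNA quality, had a median of 0.47 (adjusted p = 0.12). The list was called with the replicate block (median 0.47, adjusted p = 0.0315) and without alpha T0 replicate 2 (0.63, adjusted p = 0.0291) or asynchronous T0 replicate 1 (0.71, adjusted p = 0.0235).

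The added S. pombe cells tested whether total messenger RNA per cell changed, on the assumption, which no label states, that each sample received as many S. pombe cells per S. cerevisiae cell. S. cerevisiae counts per S. pombe count averaged 10.9 ± 1.20 before and 14.5 ± 2.65 after salt in asynchronous cells, and 9.44 ± 3.20 and 12.3 ± 4.58 in alpha factor (mean ± SD, n = 3 each). The ratio was higher after salt in each of the 3 pairs of both arms, by 1.53, 1.45 and 1.04 times and by 1.17, 1.26 and 1.43 times. Exact two-sided permutation tests gave p = 0.2 and p = 0.5 (0.1 is the smallest possible). Sign-flip tests over pairs, also exact, gave p = 0.25 for both (0.25 is the smallest possible). For arrest itself the log2 difference was -0.26 (exact two-sided permutation p = 0.7). The cycloheximide libraries, 1 per time, gave 1.11 times at 0.1 and 1.24 times at 0.2.

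On this scale the median of all genes moved by 0.60 with salt in asynchronous cells, 0.51 with salt in alpha factor and -0.25 with arrest, against 0.05, 0.00301 and -0.01 on the scale of total S. cerevisiae counts. The changes below stand against those shifts. In asynchronous cells 1209 genes were higher and 223 lower with salt (84.4% higher against 53.1%; edgeR, 5744 genes). STL1 (11.03 ± 0.64), HSP12 (10.15 ± 0.65) and CTT1 (7.88 ± 0.51) rose. RPS26B (-2.11 ± 0.51), RPL35B (-1.66 ± 0.55), UTP23 (-2.77 ± 0.61), NSR1 (-2.52 ± 0.50), HO (-3.97 ± 0.50) and AAH1 (-3.61 ± 0.50) fell, with RPL3 at -0.93 ± 0.39 (adjusted p = 0.0825, called with the replicate block). General stress genes rose in 65 of 67 (67 adjusted over the list alone), median 4.29. The adjusted p with an estimated correlation was 0.238 for this list, 0.317 for ribosomal protein and 0.317 for biogenesis genes. In alpha factor 277 genes were higher and 2 lower with salt (99.3% higher against 60.2%), the 2 being AAH1 (-2.13 ± 0.47) and IME4 (-1.81 ± 0.47), the latter not without T0 replicate 2 or 3. There general stress genes rose in 51 of 67 (58 adjusted over the list alone), median 2.28 (adjusted p = 3.07e-64, and adjusted p = 0.0784 with an estimated correlation), with STL1 (8.82 ± 0.60), HSP12 (5.73 ± 0.54) and CTT1 (5.46 ± 0.46). NSR1 was -1.45 ± 0.48 (adjusted p = 0.0878, called with the replicate block, with DESeq2 and without T0 replicate 1) and RPL3 -0.06 ± 0.39 (adjusted p = 0.934). Of 137 ribosomal protein genes 0 passed with salt in alpha factor on this scale in edgeR (0 at an unadjusted p under 0.05) and 0 in DESeq2. The list's median was 0.07 and its mean 0.09, while camera ranked it below other genes (adjusted p = 2.63e-09, and adjusted p = 0.711 with an estimated correlation); the median was -0.20 without T0 replicate 1 and -0.23 without T30 replicate 2. The biogenesis median was -0.34 (adjusted p = 9.01e-30, and adjusted p = 0.66 with an estimated correlation), but 0.079 without T30 replicate 1. For arrest 142 genes were higher and 89 lower (61.5% higher against 67.0%). FIG1 (11.41 ± 0.70), PRM3 (10.63 ± 0.81) and HSP12 (3.04 ± 0.50) were higher and PCL1 (-5.29 ± 0.95), CLB1 (-5.12 ± 0.62) and HTA2 (-4.48 ± 0.51) lower, with pheromone genes higher in 26 of 32 (30 adjusted over the list alone).

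With the replicate block the counts on the S. pombe scale were 2380 higher and 554 lower with salt in asynchronous cells, 975 and 51 in alpha factor, and 281 and 400 for arrest. Without a library they were 806 (asynchronous T30 replicate 1), 842 (T0 replicate 3), 861 (T0 replicate 2) and 903 (T0 replicate 1) in asynchronous cells. In alpha factor they were 148 (T30 replicate 2), 167 (T0 replicate 1), 183 (T0 replicate 3) and 1560 (T30 replicate 1), and for arrest 152 (alpha T0 replicate 3). RPL35B lost its call in 4 of the 6 fits without 1 asynchronous library.

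**Figure D2:**
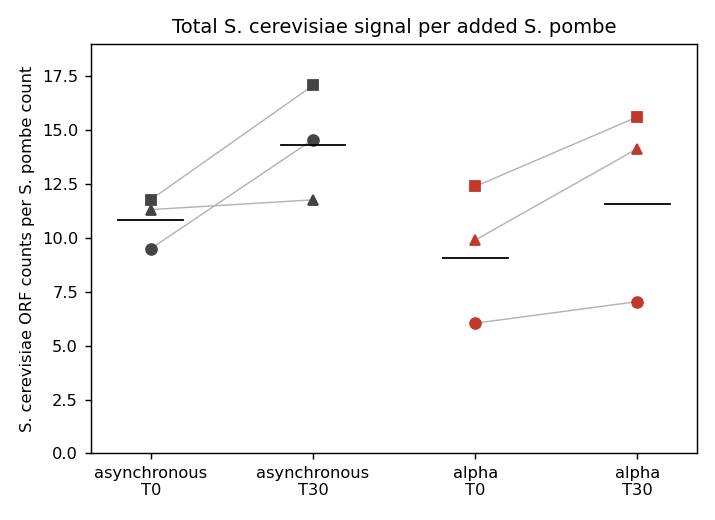
S. cerevisiae counts per S. pombe count in each spiked library. Group means were 10.9 and 14.5 in asynchronous cells and 9.44 and 12.3 in alpha factor before and after salt (n = 3 each), and lines join the replicate pairs.

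The unspiked libraries added a second arrest, in mitosis. Before salt, nocodazole cells (n = 2) against alpha-factor cells (n = 2) were higher for 22 of 29 (22 adjusted over the list alone) G2/M genes, median 1.65, with HOF1 (5.84 ± 0.47), CLB1 (5.54 ± 0.49), SWI5 (4.75 ± 0.34) and CLB2 (3.17 ± 0.30). They were lower for 29 of 32 (30 adjusted over the list alone) pheromone genes, median -3.41, with FIG1 (-10.72 ± 0.74) and FUS1 (-5.35 ± 0.31). Both calls held with either correlation (adjusted p = 4.3e-23 and 0.00103; 1.23e-50 and 0.00103). PRM6 (-11.34), PRM3 (-10.60), YCL074W (-10.02) and YCL076W (-11.19) had 1, 3, 1 and 0 counts in the 2 nocodazole libraries. This gave ratios of alpha factor to nocodazole of 3122 (560 to 123360), 1606 (549 to 7794) and 1330 (238 to 52595), and at least 180-fold higher in alpha factor for the last. IRC8 (5.35 ± 0.39) and MRH1 (4.94 ± 0.56) were also among the 5 largest rises. Histone genes were higher in 5 of 10 (8 adjusted over the list alone), HTA2 by 1.81 ± 0.31 and HHF1 by 1.76 ± 0.32 (adjusted p = 4.76e-07 and 0.00625). G1/S genes were higher in 16 of 40 (26 adjusted over the list alone) (adjusted p = 3.21e-10, and adjusted p = 0.0873 with an estimated correlation), NRM1 by 3.49 ± 0.54, and mitochondrial ribosomal proteins in 13 of 70 (29 adjusted over the list alone) (adjusted p = 3.15e-15, and adjusted p = 0.307 with an estimated correlation), MRP2 by 1.79 ± 0.37 and IMG1 by 1.38 ± 0.31. In all 233 genes were higher and 283 lower of 5836 (edgeR). The total was 248, 343, 289 and 296 without alpha T0 replicate 1, alpha T0 replicate 2, nocodazole T0 replicate 1 and nocodazole T0 replicate 2. Without the first, HHF1, IMG1 and MRP2 no longer passed, nor did IMG1 without the last.

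Salt in nocodazole (T0 n = 2, T30 n = 3, labelled 0.5N, 0.7N and without a dose) raised 865 and lowered 980 of 5836 genes (edgeR), with defense and growth lists both moving. STL1 (10.59 ± 1.68), TKL2 (9.88 ± 0.69), HXT5 (9.81 ± 0.92), ALD3 (9.24 ± 0.46), GRE1 (8.67 ± 0.62), NQM1 (8.10 ± 0.38), CTT1 (7.54 ± 0.73), HSP12 (7.45 ± 0.58) and GPD1 (3.34 ± 0.50) rose. AAH1 (-4.82 ± 0.57), the metal reductases FRE1 (-4.17 ± 0.36) and FRE7 (-3.58 ± 0.53), the copper transporter CTR1 (-3.87 ± 0.27), PHO12 (-3.60 ± 0.46), NOP7 (-3.03 ± 0.34), RPA135 (-2.89 ± 0.40), NSR1 (-2.98 ± 0.53), RPS26B (-2.32 ± 0.43), RPS16B (-2.23 ± 0.38), RPL3 (-1.61 ± 0.32) and the sterol gene ERG3 (-1.60 ± 0.41) fell. The general stress list rose in 64 of 67 (64 adjusted over the list alone), median 3.12, and osmotic genes in 24 of 31 (24 adjusted over the list alone) (adjusted p = 0.025 and 0.0424 with an estimated correlation). Ribosomal protein genes fell in 121 of 137 (127 adjusted over the list alone), median -1.35 (adjusted p = 8.21e-27 and 0.253 with an estimated correlation). Biogenesis genes fell in 120 of 129 (125 adjusted over the list alone), median -1.88 (adjusted p = 1.11e-36 and 0.169 with an estimated correlation). The mitochondrial ribosomal protein MRP2 (-0.84 ± 0.30) lost its call without each of the libraries except the 0.5N one, and with DESeq2, RLE size factors, no filter or only the compared libraries. The count was 993 without nocodazole T0 replicate 1.

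Salt in alpha factor without added cells (T0 n = 2, T30 n = 3) raised 189 and lowered 153 of 5836 genes (edgeR). STL1 (8.14 ± 1.57), TKL2 (6.75 ± 0.62), YER053C-A (6.04 ± 1.24, 1 count over the 2 libraries before salt, ratio 77.8, 13.7 to 3093), SPS100 (5.11 ± 0.55), HSP12 (5.10 ± 0.52), YGP1 (4.79 ± 0.41), CTT1 (4.22 ± 0.62) and GPD1 (2.15 ± 0.47) rose. So did HTA2 (1.31 ± 0.29) and the cyclins PCL1 (2.55 ± 0.71), CLN1 (1.23 ± 0.35) and CLB5 (1.14 ± 0.23), while the G1/S list had a median of -0.10 (adjusted p = 0.464). AAH1 (-2.86 ± 0.47), IME4 (-2.35 ± 0.30), FRE7 (-2.21 ± 0.50), the S-adenosylmethionine synthetase SAM1 (-2.02 ± 0.35), CTR1 (-2.01 ± 0.26), DBP2 (-1.70 ± 0.32) and NSR1 (-1.81 ± 0.51, adjusted p = 0.0496) fell, as did the mitochondrial gene COB (-1.37 ± 0.33), not without T0 replicate 1 or either dose library, and RPL3 was -0.48 ± 0.32 (adjusted p = 0.443). The genes encoded in mitochondria, a check of RNA quality, fell in 1 of 8 (4 adjusted over the list alone), median -1.03 (adjusted p = 0.00172, and adjusted p = 0.252 with an estimated correlation). General stress genes rose in 39 of 67 (56 adjusted over the list alone), median 1.58, and histone genes in 2 of 10 (8 adjusted over the list alone) (adjusted p = 0.025 and 0.025 with an estimated correlation). Biogenesis genes fell in 24 of 129 (73 adjusted over the list alone), median -0.91 (adjusted p = 3.36e-25, and adjusted p = 0.252 with an estimated correlation). Of 137 ribosomal protein genes 0 passed in edgeR, over all genes or the list alone (0 at an unadjusted p under 0.05), and 0 in DESeq2. The list median was -0.13 (adjusted p = 0.0909), but -0.31 (adjusted p = 0.000138) without the 0.5N libraries and -0.20 (adjusted p = 0.00569) without T0 replicate 1. Of the 188 higher genes that were tested in the spiked libraries too, 152 were also higher there (10.3 by chance), and of 153 lower genes 80 (5.58 by chance). The count was 78, 105, 128 and 203 without T0 replicate 1, T0 replicate 2, the 0.7N library and T30 replicate 1, with 11, 7, 6 and 3 of the 20 named genes losing their call, and 3 without the 0.5N library. DESeq2 called 525, the replicate block 541 and the fit without the 0.5N libraries 542.

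The difference between the 2 arrests in their salt response was tested on the same libraries. 104 genes responded higher and 34 lower in nocodazole than in alpha factor (edgeR, 5836 genes). Higher were HXT5 (5.60 ± 1.01), CPP3 (5.30 ± 0.76), NQM1 (5.02 ± 0.40), PHM7 (4.45 ± 1.12), ALD3 (4.44 ± 0.47), ENA1 (4.22 ± 0.97), GRE1 (3.96 ± 0.81), CTT1 (3.32 ± 0.77) and HSP12 (2.36 ± 0.59). Lower were PHO12 (-3.02 ± 0.66), PHO11 (-2.66 ± 0.59), MRH1 (-2.61 ± 0.63), LEU9 (-2.60 ± 0.61), YGL123C-A (-3.40 ± 0.77), RPS16B (-2.27 ± 0.54), RPL26B (-1.83 ± 0.45) and RRP36 (-2.08 ± 0.47). RPL3 (-1.13 ± 0.46), NSR1 (-1.17 ± 0.74), GPD1 (1.19 ± 0.61) and STL1 (2.45 ± 2.22) did not pass. General stress genes were higher in 26 of 67 (45 adjusted over the list alone), median 1.51 (adjusted p = 4.17e-30, and adjusted p = 0.0869 with an estimated correlation). Ribosomal protein genes were lower in 6 of 137 (96 adjusted over the list alone), median -1.27 (adjusted p = 7.26e-35, and adjusted p = 0.202 with an estimated correlation). Biogenesis genes were lower in 1 of 129 (0 adjusted over the list alone), median -1.03 (adjusted p = 5.18e-22, and adjusted p = 0.255 with an estimated correlation). The genes encoded in mitochondria also moved, with median 1.01 (adjusted p = 0.0174, and adjusted p = 0.338 with an estimated correlation). Of these 8 genes 0 passed in edgeR (2 higher at an unadjusted p under 0.05) and 0 in DESeq2. The list lost its call without alpha T0 replicate 1 (median 0.52, adjusted p = 0.0946) and without both 0.5N libraries (0.75, adjusted p = 0.0809). With salt its median was -1.03 in alpha factor and 0.02 in nocodazole (adjusted p = 0.95).

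In this difference single genes depended on single libraries, and the list medians less so. The count was 12, 16, 43, 44, 48, 48, 67, 87 and 730 without nocodazole T0 replicate 1, alpha T0 replicate 1, nocodazole T0 replicate 2, alpha T0 replicate 2, alpha 0.5N, nocodazole 0.7N, nocodazole T30 replicate 1, alpha T30 replicate 1 and nocodazole 0.5N. It was 503 (223 higher and 280 lower) without both 0.5N libraries, 315 with DESeq2 and 331 with a replicate block. CPP3, NQM1 and ALD3 passed without each of these libraries, while 14, 14, 13, 13, 11, 12, 12 and 9 of the 17 named genes did not without the first 8 libraries and 4 did not without alpha 0.7N.

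**Figure D3:**
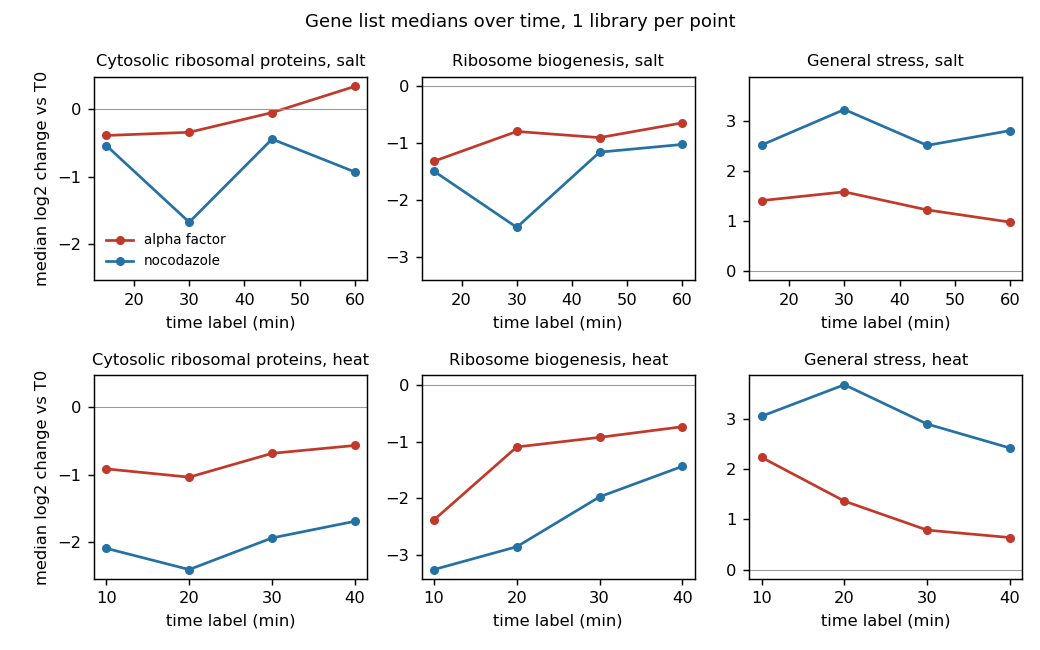
Median log2 change of ribosomal protein, biogenesis and stress lists over time, 1 library per time. With salt the ribosomal protein median was -0.39, -0.34, -0.05 and 0.34 at 15, 30, 45 and 60 min in alpha factor and -0.54, -1.68, -0.45 and -0.93 in nocodazole.

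Time courses and doses had 1 library per point and so no test; each list's median is set against 10000 random lists of matched level. With salt in alpha factor the general stress median was 1.41, 1.58, 1.22 and 0.98 at 15, 30, 45 and 60 min, above every random list, and the biogenesis median -1.32, -0.79, -0.90 and -0.64, below every one. The ribosomal protein median was -0.05 at 45 min (percentile 29.6) and 0.34 at 60 min (percentile 100). In nocodazole the same lists stood at 2.52, 3.22, 2.51 and 2.80 for stress and -1.49, -2.48, -1.16 and -1.02 for biogenesis. At the labels 0.5N and 0.7N the stress median was 1.07 and 1.85 in alpha factor and 2.44 and 3.0 in nocodazole, and the ribosomal protein median 0.08 and -0.22 against -0.79 and -1.71.

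Longer mitotic arrest and slowed translation were tested next. After 3.5 h in nocodazole (n = 2 and 2) salt raised 822 and lowered 857 of 5836 genes (edgeR). STL1 (12.48 ± 1.84), TKL2 (9.84 ± 0.69), HXT5 (9.53 ± 0.89), SPS100 (8.82 ± 0.67), ALD3 (8.30 ± 0.44), CTT1 (7.23 ± 0.73), HSP12 (4.90 ± 0.52) and GPD1 (3.53 ± 0.52) rose. CTR1 (-3.70 ± 0.32), AAH1 (-3.43 ± 0.65), PHO12 (-3.40 ± 0.55), PHO11 (-3.03 ± 0.44), DHR2 (-3.17 ± 0.62), NSR1 (-2.64 ± 0.61), RPS26B (-2.55 ± 0.50) and RPL3 (-1.44 ± 0.36) fell. General stress genes rose in 61 of 67 (64 adjusted over the list alone), median 2.55, and osmotic genes in 25 of 31 (26 adjusted over the list alone) (adjusted p = 0.0292 and 0.0292 with an estimated correlation). Ribosomal protein genes fell in 90 of 137 (109 adjusted over the list alone), median -1.18 (adjusted p = 2.01e-20 and 0.339 with an estimated correlation). Biogenesis genes fell in 110 of 129 (120 adjusted over the list alone), median -1.59 (adjusted p = 3.85e-31 and 0.201 with an estimated correlation). Mitochondrial ribosomal proteins fell in 40 of 70 (53 adjusted over the list alone), median -0.85 (adjusted p = 2.63e-13, and adjusted p = 0.257 with an estimated correlation), with MRPL49 (-1.52 ± 0.28), MRPS16 (-1.46 ± 0.33) and MRPL11 (-1.36 ± 0.23). The count was 872, 988 and 1038 without T0 replicate 1, T0 replicate 2 and T30 replicate 1, and 915 when these 4 libraries were fitted alone. RPL3 lost its call in that last fit and without T0 replicate 1 or T30 replicate 2.

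In cycloheximide at the label 0.1 (n = 2 and 2) salt raised 951 and lowered 1014 of 5836 genes (edgeR). STL1 (11.79 ± 1.75), YNL194C (9.84 ± 1.31), HSP12 (9.41 ± 0.65), FMP48 (9.41 ± 1.24), HXT5 (9.39 ± 0.91), CTT1 (7.26 ± 0.73), GPD1 (5.75 ± 0.58), HSP26 (4.94 ± 0.47) and SSA4 (4.59 ± 0.41) rose. PHM6 (-4.11 ± 0.48), SFG1 (-3.95 ± 0.24), PHO84 (-3.81 ± 0.60), NSR1 (-3.78 ± 0.64), HO (-3.66 ± 0.43), CLB2 (-2.40 ± 0.29), AMN1 (-2.65 ± 0.35), RPS26B (-2.15 ± 0.48) and RPL18B (-1.78 ± 0.30) fell, with RPL3 at -0.92 ± 0.36 (adjusted p = 0.0564). RPL3 was called with the replicate block, with DESeq2 and without T30 replicate 1. With cycloheximide general stress genes rose in 65 of 67 (66 adjusted over the list alone), median 3.86, and osmotic genes in 24 of 31 (24 adjusted over the list alone) (adjusted p = 0.0192 and 0.0465 with an estimated correlation). Heat shock factor targets rose in 17 of 33 (17 adjusted over the list alone) (adjusted p = 9.36e-06, and adjusted p = 0.0995 with an estimated correlation). Biogenesis genes fell in 125 of 129 (126 adjusted over the list alone), median -1.76 (adjusted p = 7.76e-30 and 0.127 with an estimated correlation). Ribosomal protein genes fell in 59 of 137 (80 adjusted over the list alone), median -0.93 (adjusted p = 1.05e-13 and 0.364 with an estimated correlation). M/G1 genes fell in 15 of 25 (16 adjusted over the list alone), median -0.93 (adjusted p = 9.36e-06, and adjusted p = 0.0875 with an estimated correlation). The 4 libraries fitted alone gave 1060 genes. At 0.2, with 1 library per time, the stress, ribosomal protein and biogenesis medians were 3.59, -0.83 and -1.36.

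Across all genes the salt responses were alike in direction. Against asynchronous cells, r was 0.927 for cycloheximide at 0.1, 0.884 for nocodazole, 0.860 for nocodazole at 3.5 h (5708 genes each) and 0.726 for alpha factor (5744 genes). Of the 314 genes higher with salt in alpha factor 265 were also higher in asynchronous cells (69.7 by chance), and of 208 lower genes 167 (40.7 by chance), with 6 called in opposite directions. For nocodazole 747 of 857 higher genes and 806 of 979 lower genes were shared (191 and 193 by chance), and for cycloheximide 835 of 938 and 790 of 1012 (209 and 199 by chance). Among genes changed at least 2-fold in asynchronous cells the median change relative to theirs was 0.92 for higher and 0.79 for lower genes in cycloheximide, 0.75 and 0.86 in nocodazole, 0.69 and 0.74 at 3.5 h, and 0.40 and 0.39 in spiked alpha factor. Over all these genes the nocodazole libraries differed, at 0.53 for 0.5N and 0.90 and 0.92 for the others. As these genes were chosen for a large asynchronous change, a no-change value was taken from genes chosen in 2 asynchronous pairs and read in the pair held out. It was 1.03, 0.84 and 0.98 for higher and 1.17, 0.72 and 1.05 for lower genes, ranges that hold both cycloheximide values and the nocodazole values for lower genes. These comparisons come from separate series for all but alpha factor, and their differences from asynchronous cells were not tested.

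Heat shock at T10 asked the same of another stress. In alpha factor (T0 n = 2, T10 n = 3, labelled 33c, 37c and without a temperature) heat raised 401 and lowered 469 of 5689 genes (edgeR). SSA4 (7.94 ± 1.04), HSP26 (7.57 ± 0.97), DDR2 (6.63 ± 0.86), YGP1 (5.40 ± 0.56), SPI1 (5.25 ± 0.78), HSP30 (4.96 ± 1.18), the sorting factor BTN2 (4.49 ± 1.07), HSP12 (4.93 ± 0.71) and CTT1 (2.31 ± 0.60) rose. RPF1 (-3.06 ± 0.70), DHR2 (-2.98 ± 0.32), NOP14 (-2.96 ± 0.51), YBL028C (-2.96 ± 0.58), NOP13 (-2.72 ± 0.42), RPA43 (-2.26 ± 0.32), NSR1 (-1.89 ± 0.31), RPL31B (-1.92 ± 0.35), RPS26B (-1.72 ± 0.36) and RPL3 (-1.03 ± 0.25) fell, with GPD1 at 0.35 ± 0.29 (adjusted p = 0.46). General stress genes rose in 53 of 67 (60 adjusted over the list alone), median 2.20, and polymerase I and III genes fell in 18 of 21 (19 adjusted over the list alone), median -1.53 (adjusted p = 0.0436 and 0.0436 with an estimated correlation). Heat shock factor targets rose in 25 of 33 (28 adjusted over the list alone), median 2.31 (adjusted p = 1.14e-16, and adjusted p = 0.272 with an estimated correlation). Biogenesis genes fell in 108 of 129 (120 adjusted over the list alone), median -1.90 (adjusted p = 9.07e-45, and adjusted p = 0.0813 with an estimated correlation). Ribosomal protein genes fell in 28 of 137 (31 adjusted over the list alone), median -0.94 (adjusted p = 1.53e-13, and adjusted p = 0.46 with an estimated correlation). The count was 265, 387 and 402 without T0 replicate 1, the 37c library and T10 replicate 1, and 9, 5 and 5 of the 19 named genes no longer passed, as did 3 without T0 replicate 2.

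In nocodazole (T0 n = 2, T10 n = 3) heat raised 928 and lowered 954 of 5689 genes (edgeR). SSA4 (8.44 ± 1.06), HSP26 (8.20 ± 1.0), the hexose transporter HXT7 (7.65 ± 0.85), TMA10 (7.18 ± 0.96), SPI1 (6.89 ± 0.86), HSP12 (6.68 ± 0.77), CTT1 (4.06 ± 0.66) and GPD1 (1.96 ± 0.31) rose. DHR2 (-5.44 ± 0.37), RPA43 (-5.12 ± 0.37), BRX1 (-4.84 ± 0.31), UTP13 (-4.70 ± 0.28), RIX1 (-4.69 ± 0.31), NSR1 (-4.02 ± 0.34), RPS26B (-2.65 ± 0.36), RPL3 (-1.26 ± 0.25), ERG3 (-2.47 ± 0.28) and ERG11 (-1.70 ± 0.24) fell. STL1, at 13.0 ± 11.8 before and 2.30 ± 1.75 CPM after heat, fell (-2.31 ± 0.71) but not without T0 replicate 1, T10 replicate 1 or the 37c library. The general stress list rose in 62 of 67 (63 adjusted over the list alone), median 3.34, and polymerase I and III genes fell in 20 of 21 (20 adjusted over the list alone), median -2.27 (adjusted p = 0.0493 and 0.0493 with an estimated correlation). Heat shock factor targets rose in 29 of 33 (31 adjusted over the list alone), median 2.89 (adjusted p = 1.61e-13, and adjusted p = 0.328 with an estimated correlation). Biogenesis genes fell in 123 of 129 (125 adjusted over the list alone), median -3.37 (adjusted p = 6.01e-47, and adjusted p = 0.0737 with an estimated correlation). Ribosomal protein genes fell in 84 of 137 (96 adjusted over the list alone), median -1.47 (adjusted p = 1.18e-18, and adjusted p = 0.328 with an estimated correlation). The count was 1209 without T0 replicate 1.

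The heat response of the 2 arrests differed for 45 higher and 33 lower genes in nocodazole (edgeR, 5689 genes). BAG7 (6.41 ± 0.65), the Rab GTPase YPT53 (5.80 ± 1.12, 2 counts over the 2 nocodazole libraries before heat, ratio 88.1, 24.2 to 731), the pyruvate carrier MPC3 (3.52 ± 0.39), RGI1 (3.35 ± 0.65) and RTA1 (3.11 ± 0.60) were higher. YGP1 (-3.77 ± 0.64), NCE102 (-3.43 ± 0.52), SFG1 (-3.16 ± 0.47), AIM20 (-2.94 ± 0.43), RPA43 (-2.86 ± 0.49), UTP13 (-2.81 ± 0.38) and BRX1 (-2.62 ± 0.41) were lower, with HSP12 (1.75 ± 0.81) and CTT1 (1.74 ± 0.81) not passing. General stress genes were higher in 9 of 67 (30 adjusted over the list alone), median 1.26 (adjusted p = 1.46e-20, and adjusted p = 0.105 with an estimated correlation). Biogenesis genes were lower in 12 of 129 (70 adjusted over the list alone), median -1.30 (adjusted p = 3.5e-36, and adjusted p = 0.105 with an estimated correlation). The ribosomal protein median was -0.66 with 0 genes passing in edgeR (3 lower at an unadjusted p under 0.05) and 0 in DESeq2 (adjusted p = 2.62e-08, and adjusted p = 0.488 with an estimated correlation).

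The count of genes whose heat response differed hung on single libraries. It was 0 without nocodazole T0 replicate 1 or 2, 2 without nocodazole 37c or alpha T0 replicate 2, 3, 5, 6, 11 and 48 without alpha T10 replicate 1, alpha T0 replicate 1, alpha 33c, alpha 37c and nocodazole T10 replicate 1. It was 2 without both 33c libraries, and 284 with DESeq2 and 226 with a replicate block over all libraries. Of the 12 named genes 12, 12, 10, 10, 9, 9, 9, 8, 3 and 11 no longer passed without these libraries, in the same order.

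Gradients asked if salt moved messages into or out of the fractions from 2R up, not on or off ribosomes. With fraction counts scaled to S. pombe RNA, on the assumption that each fraction received an equal amount, the fractions from 2R up held 40.6% and 37.9% of S. cerevisiae counts before and 47.1% and 34.4% after salt in asynchronous cells, and 50.8% in the alpha-factor gradient. Per gene, the log2 ratio of counts in these fractions to counts in the lighter ones (the polysome ratio) was compared in 5053 genes (limma, n = 2 and 2). 116 were higher and 9 lower after salt (944 and 89 with the replicate block), with a median shift of 0.36 over all genes, 92.8% higher against 60.9% (783 and 502 genes, shift 0.08) when fractions were scaled by TMM. Of the 116 higher genes 61 had under 10 CPM in the T0 inputs, so they met the input minimum only through T30. These included the 5 largest rises, STL1, SPG4, SPI1, FMP16 and EGO4 (21, 11, 250, 68 and 57 counts over the T0 fractions), and CTT1, NQM1 and HSP30. Their changes, and that of HSP12 (4.69 CPM in the T0 inputs), are not reported here. Among 4714 genes with at least 10 CPM in the inputs of each time, a test chosen after the data were seen, 46 were higher and 7 lower. SSA4 (2.34) had a higher ratio, and so had the a-factor gene MFA1 (1.62), but not in that test (adjusted p = 0.0578). TOS6 (-2.70), the cell wall proteins CCW12 (-2.56) and CIS3 (-2.13), NSR1 (-2.31), RPL22B (-2.05) and RPL7B (-1.73) had a lower one in both tests. GPD1 (1.32) and RPL3 (-0.85) did not pass. All shared 1 SE (0.49), so calls do not rest on a gene's own spread. RPL3 was called with the replicate block and with TMM scaling of fractions, and GPD1 with the block and without T30 replicate 2. With at least 10 CPM at each time general stress genes were higher in 8 of 48, median 0.85 (adjusted p = 1.64e-07), and osmotic genes in 2 of 19, median 0.51 (adjusted p = 0.0029), both at adjusted p = 0.962 with an estimated correlation. Ribosomal protein genes were lower in 2 of 137 (2 adjusted over the list alone) with median 0.04 and mean 0.01. Camera ranked the list below other genes (adjusted p = 1.39e-06 and 0.926 with an estimated correlation). Biogenesis genes were lower in 1 of 128 (1 adjusted over the list alone), median -0.13 (adjusted p = 1.79e-10 and 0.926 with an estimated correlation).

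The count for the polysome ratio was 14, 42, 89 and 737 without T0 replicate 2, T0 replicate 1, T30 replicate 1 and T30 replicate 2. The first 3 took 7, 7 and 1 of the 16 genes called under the naming rule. It was 0 with no filter on low values, where none of the 16 passed and 587 genes had an unadjusted p under 0.05. The ratio of the heaviest fraction to input (6R> to Input, n = 2 per group) differed with salt for 0 of 5348 genes in edgeR (233 at an unadjusted p under 0.05) and 0 in DESeq2 (216 unadjusted), and for 76 without the T30 input replicate 1. Scaling these libraries to S. pombe RNA moved the median of all genes from 0.05 to -0.62. The ribosomal protein median in that ratio was 0.90 (adjusted p = 2.42e-18, and adjusted p = 0.889 with an estimated correlation). The biogenesis median was -1.55 (adjusted p = 4.11e-22, and adjusted p = 0.889 with an estimated correlation), with NSR1 at -2.69 ± 0.67 and RPL3 at 0.61 ± 0.65.

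**Figure D4:**
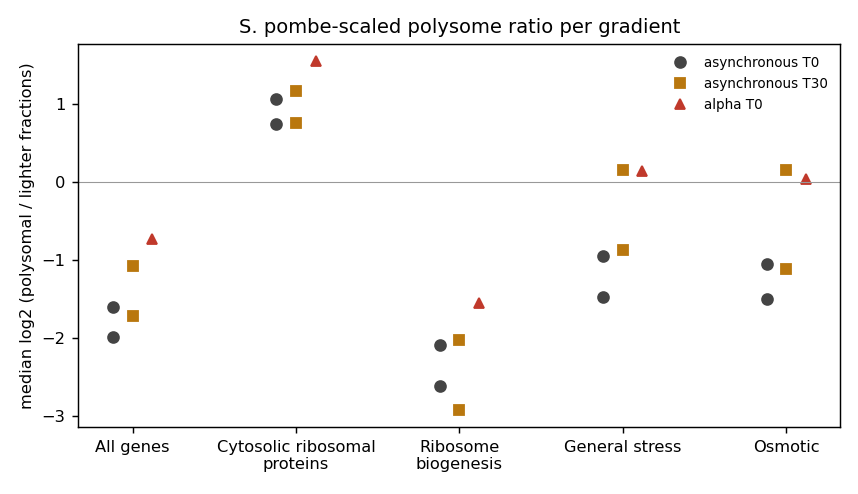
Median log2 ratio of counts in fractions 2R and above to those in lighter fractions, per gradient, over all genes and by list. With salt in asynchronous cells 116 of 5053 genes had a higher and 9 a lower ratio (n = 2 and 2), with SSA4 at 2.34 and NSR1 at -2.31.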

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

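All tests of explanations in this part were chosen only after the result was seen, apart from the splits of the samples. 3 results stand out because the response of 2 groups differed by a direct test: 505 genes for salt between alpha factor and asynchronous cells, 138 for salt between nocodazole and alpha factor, and 78 for heat between nocodazole and alpha factor. 2 more come from libraries that no comparison of the report uses: in the t0' libraries of the alpha-factor salt and heat series the pheromone list had medians of -3.58 and -3.24 against T0, below each of 10000 random lists.

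The smaller salt response of alpha-arrested than of asynchronous cells was weighed first. With S. pombe scaling the difference of the general stress list was -1.93, with pair medians of 1.77, 2.68 and 2.33 in alpha factor against 4.47, 4.25 and 3.88, which argues against scaling to total S. cerevisiae counts as the cause. A higher level before salt was tested at T30, where the list was lower in alpha factor than in asynchronous cells by a median of -0.85 (1 of 67 genes higher and 32 lower), which argues against a higher starting level as the whole cause. Before salt the list was 0.87 higher in arrest. The response difference (-1.90) subtracts that level, so its part in the cause stays open. Without alpha T30 replicate 2, which stands apart, the difference was -1.75. A dependence of the stress response on the state of the cells may explain it, but alpha factor as a drug and signal, and not only arrest, stays open as untested.

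The larger salt response of nocodazole- than of alpha-arrested cells held at each dose label. There the smallest of 3 general stress differences, sharing T0 libraries, was 1.49. Without any 1 library the lowest was 1.33. These argue against mixed doses and a single library. In pairs outside that comparison the share of the asynchronous change kept was 0.777 and 0.658 in the 2 pairs at 3.5 h in nocodazole and 0.359, 0.434 and 0.349 in the 3 spiked alpha-factor pairs. The lowest of the first lay 0.224 above the highest of the second (larger SD 0.0840), which argues against arrest of division as such setting the size of the response. The stage of arrest, other drug effects and the level before salt (stress list median -0.27, nocodazole minus alpha) stay open as untested. Kept shares used spiked asynchronous cells, not the 1 unspiked asynchronous library per time.

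The higher G1/S genes with salt in alpha-arrested cells may rest on 1 library. Without alpha T30 replicate 2 the list median was -0.059. In the unspiked series the list median was -0.10 (adjusted p = 0.464), but PCL1, CLN1 and CLB5 rose there too, so for these genes a rise does not rest on that library alone. CLN1 lost that call without any 1 unspiked library, PCL1 without any but T30 replicate 1, and CLB5 without T0 replicate 1. A swapped asynchronous library is argued against by the pheromone median of 8.22, which lay 2.57 above the highest asynchronous library (5.65) and below the other alpha-factor libraries (8.84 to 9.64). Asynchronous cells mixed into the sample were not told apart from cells leaving arrest. The pheromone genes allow a share of 0.781, which may count their fall with salt as admixture. At that share the library's G1/S list lay -0.21 (median) from the highest level allowed, with 12 of 40 genes above. CLB6, 1 of them, was at 76.3 CPM against at most 27.2 in asynchronous libraries.

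The splits of 3 against 3 samples number 10, too few for a share under 0.05. The real split was the 1 largest for salt in asynchronous cells (2399, highest other 0), salt in alpha factor (522, highest other 0), arrest (737, highest other 0), and, scaled to S. pombe, salt in asynchronous cells (1432, highest other 0) and arrest (231, highest other 0). For the difference between the arms, fitted with the pairs, it was the 1 largest of 10 assignments (1729, highest other 0). For salt in alpha factor scaled to S. pombe 2 of 10 splits were as large as the real 279, the other calling 3434, which points to a structure of the samples; it parts 1 pair, while among the 4 splits that part all 3 pairs the highest other was 0.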

How the results depend on the processing

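The alternatives were fixed before the data were examined, except the S. pombe scaling of the difference between arms, the crossed pairing and the input minimum at each time, tests chosen only after the data were seen; the cause of each change below was not tested unless stated. Where an arm was left with 1 library, that library was assumed to vary like the other groups. Among 4239 alternative values of named genes 3743 were the same in call, 469 weaker, 27 stronger and 0 reversed. For 3906 list medians these counts were 3730, 76, 97 and 3. Sign changes without calls in both fits were not counted as reversed. Rows beyond ORFs could not give another value and were not run. In the 6R> to Input ratio 0% of simulated 2-fold and 11% of 4-fold changes were recovered. Depth limits the polysome ratio before salt, where 293 of 5053 genes had under 10 CPM in the T0 inputs.

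With a 2-fold minimum, which by construction passes fewer genes, salt gave 1525 genes in asynchronous cells, 342 in alpha factor and 1209 in nocodazole. DESeq2 gave 758 for the difference between arms, 525 for unspiked alpha factor, 315 for nocodazole minus alpha factor and 284 for the same with heat. With S. pombe scaling the difference between arms was 68. Fitting only the libraries compared gave 2506 (asynchronous salt scaled to S. pombe), 358 (arrest scaled to S. pombe), 1024 (unspiked alpha factor), 915 (nocodazole at 3.5 h), 1060 (cycloheximide) and 1509 (nocodazole against alpha factor). Without the 0.5N libraries unspiked alpha factor gave 542 and nocodazole minus alpha factor 503, and without the 33c libraries the heat difference gave 2. With no filter on low counts the 6R> to Input ratio gave 5 genes and the polysome ratio 0. TMM scaling of fractions gave 1285, and at least 10 CPM in the inputs of each time, which tests fewer genes, gave 53. Of 250 list calls by camera 39 held with an estimated correlation, and fry called 172.

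A replicate block, in the spiked series where the numbers pair the samples, gave 1722 for salt in alpha factor, 1800 for the difference between arms, 1719 for arrest, and on the S. pombe scale 2934, 1026 and 681. In cycloheximide and 3.5 h nocodazole, where the numbers pair the samples too, it gave 2432 and 2127, and with heat in nocodazole 2345, all within 1.5 times the count without it. It changed no other call of a named gene there than that of RPL3 in cycloheximide. In the other salt libraries (correlations of libraries with the same number from -0.441 to 0.544), for alpha T10 in heat (-0.512 to 0.376) and in the 6R> and input libraries (-0.136 to 0.367) the numbers do not pair all samples. For the polysome ratio the correlation was 0.195, which with 2 pairs leaves the pairing open. The block gave 541 for unspiked alpha factor, 331 and 226 for nocodazole minus alpha factor with salt and heat, and 1033 for the polysome ratio. A crossed pairing of nocodazole and alpha factor T0 gave 720 against 717 with the numbers as labelled.

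Leaving out 1 library gave lowest and highest counts of 199 and 409 (salt in alpha factor), 236 and 713 (difference between arms), 484 and 650 (arrest), 806 and 1166, 148 and 1560, and 152 and 219 (salt in asynchronous cells, salt in alpha factor and arrest on the S. pombe scale), 78 and 315 (unspiked alpha factor), 993 and 2140 (nocodazole), 12 and 730 (nocodazole minus alpha factor), 872 and 1978 (nocodazole at 3.5 h), 248 and 343 (nocodazole against alpha factor before salt), 265 and 766 (heat in alpha factor), 1209 and 1945 (heat in nocodazole), 0 and 106 (heat difference), 0 and 76 (6R> to Input) and 14 and 737 (polysome ratio). It gave 1999 to 2277 for salt in asynchronous cells and 1454 to 1797 for cycloheximide. On the S. pombe scale in alpha factor the ribosomal protein median of 0.07 reversed to -0.20 and -0.23 (range -0.23 to 0.42) and the biogenesis median of -0.34 to 0.079 (range -0.69 to 0.079). The log2 difference of total ratios ranged over 0.28 to 0.54, 0.07 to 0.72 and -0.48 to 0.03 for salt in asynchronous cells, salt in alpha factor and arrest.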

Other observations

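The t0' libraries, 1 each in 4 series and in no comparison of the report, differed from the T0 libraries of their series in cell cycle and stress genes. In the alpha-factor salt and heat series, against T0, histone genes stood at 2.76 and 3.19, G2/M genes at 1.19 and 1.20, general stress genes at -1.61 and -1.52 and ribosomal protein genes at 0.42 and 0.58. In the nocodazole salt and heat series histone genes stood at 1.76 and 1.19, G2/M genes at -0.65 and -0.59 and general stress genes at -0.87 and -0.67.

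At T30 with salt, alpha-factor and asynchronous cells differed in 430 higher and 287 lower of 5744 genes (edgeR). The heaviest fraction held 15.97% and 10.6% of scaled counts before and 27.5% and 13.1% after salt in asynchronous cells, and 23.9% in the alpha-factor gradient.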
